A study of Homo sapiens with 6 samples.

How the data were processed

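Messenger RNA of 6 HCT116 samples was measured, 3 with an empty vector and 3 with SETD8 overexpression. Per the labels' protocols, RNA was extracted with TRIzol and poly(A)-selected libraries were made with the Illumina TruSeq Stranded mRNA kit. The deposited table holds whole-number read counts per gene, not normalized, for 58735 Ensembl gene IDs. The submitters' processing notes name HISAT2, STAR, featureCounts, HTSeq, GRCh38 and hg38, with no role or version. Which aligner and counter made the table, the annotation and the strand setting are not given in the sources used here. All 58735 IDs match GENCODE release 29 (GRCh38), which gave positions, lengths and GC content, and 58207 had a current symbol. No row lacked a gene ID and 0 columns belonged to other samples.

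Columns were matched to samples by name. The columns of one group are named NC with a number, and they were taken as the vector group because it is the only group other than SETD8, with the number as the replicate. Totals per library were 17056672 to 20471843 counts. Tested genes held 99.9% of the counts in each library.

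Genes were filtered with filterByExpr on the group, which left 14370 and dropped 44365. Library sizes were scaled by TMM, and the groups were compared, without covariates, by edgeR's robust quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The biological coefficient of variation was 0.116. The SE of a log2 fold change is its size divided by the square root of its F statistic. CPM values are TMM-normalised, with a prior count of 2 for log CPM. Because the kit marks strand but the counting setting is not known, values of antisense and overlapping genes are uncertain. Those of genes with near-identical copies are uncertain as well. Some such genes are marked in the text, but genes were not searched for overlap or copies, so an unmarked gene may have either.

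Before the data were examined, 29 gene lists were fixed. They covered YAP/TAZ targets, Hippo components, H4K20 methylation with methyltransferases, the ligase of SETD8, p53, mitosis, replication, histones, Wnt, MAPK, NF-kappaB and interferon. Further lists covered hypoxia, NRF2, ATF4, endoplasmic reticulum chaperones, heat shock, cholesterol, oxidative phosphorylation, mitochondrial messengers and ribosomal proteins. The rest held epithelial, mesenchymal and intestinal genes, nuclear noncoding RNAs, and HEK293, fibroblast, endothelial and immune markers. The 26 lists with at least 5 tested members were tested with camera (inter-gene correlation 0.01), adjusted over the lists. Camera was repeated with an estimated correlation, under which 0 of the 10 called lists kept the call, and fry, which called 1 list for movement in one direction and 19 for change in either direction. Named genes were also fixed then. They were 10 genes of the SETD8 and YAP pathway, the 10 largest rises and 10 largest falls among genes with a symbol, mean CPM of at least 5 and groups that did not overlap, and up to 4 members of each list by adjusted p. Genes named outside this rule are marked in the text, and some that the rule selects are not reported here.

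The alternatives, also fixed before the data were examined, were DESeq2-type size factors, library totals, KMT5A left out, no low-count filter, a stricter filter (1 CPM in all 3 libraries of a group), DESeq2 1.42.0, limma-voom, a replicate block and leaving out each library. GC and length corrections, which remove each library's trend by lowess offsets (span 0.3), were added after seeing the data. On simulated data with 200 changed genes among 14370 in each of 5 runs of the vector against SETD8 comparison, the test recovered 55.0% of genes changed 1.5-fold, 80.8% at 2-fold and 94.5% at 4-fold, and 3.54% of its calls were unchanged genes. Camera called 0 of 125 unchanged lists and 5 of 5 shifted lists. Simulated genes were drawn independently, with the same dispersion in both groups. These rates therefore do not cover correlated genes or groups of unequal spread. Single shares of a library were compared by exact permutation tests. Figures were drawn with matplotlib 3.10.9.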

Results

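RNA sequencing compared HCT116 cells, an established human colorectal carcinoma line, that carried an empty vector with HCT116 cells that overexpressed SETD8, a histone lysine methyltransferase whose gene now has the symbol KMT5A. The title of the series concerns methylation of the transcriptional coactivator YAP by SETD8 and the loss of YAP protein, and the comparison asks which transcripts differ between the cell populations. The labels give 3 vector and 3 SETD8 libraries, made from poly(A)-selected RNA with a strand-marking kit. One label describes lentiviral transduction and selection with puromycin, while the design text speaks of transfection. Vector replicates 1, 2 and 3 held 19031153, 20471843 and 17187722 counted reads, and SETD8 replicates 1, 2 and 3 held 18785454, 18784134 and 17056672. A gene with 3 counts in a library stood at 0.15 to 0.17 CPM, the normalised read count scaled to library size. Such floors cover counting error only. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

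The SETD8 libraries lay close together and the vector libraries were spread out. On the first principal component of log2 CPM, which held 46.4% of the variance, SETD8 replicates 1, 2 and 3 stood at -23.7, -16.5 and -23.8. Vector replicates 2 and 3 stood at 25.7 and 39.3, and vector replicate 1 stood between the groups at -0.94. The chi-square per degree of freedom between pairs of libraries was 6.17 to 8.77 within the SETD8 group and 14.0 to 34.0 within the vector group, so no pair agreed within sampling noise. Vector replicate 1 gave 13.3, 12.3 and 11.6 against SETD8 replicates 1, 2 and 3, lower than its 14.0 and 34.0 against vector replicates 2 and 3. Pairs of vector replicate 2 or 3 with a SETD8 library gave 28.8 to 53.9. Mitochondrial transcripts took 6.60% ± 1.02 of the counts in vector libraries and 5.07% ± 0.25 in SETD8 libraries (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The mitochondrial ribosomal RNA MT-RNR2, named after its value was seen, took 2.32% ± 0.54 and 1.43% ± 0.19 (exact permutation p = 0.1).

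**Figure D1:**
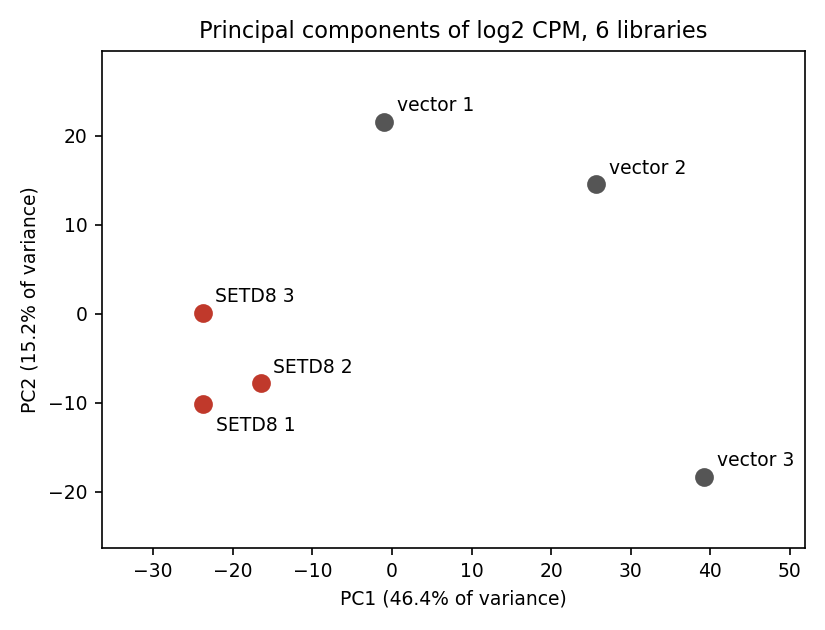
Principal components of log2 CPM for the 6 libraries, with PC1 (46.4% of the variance) on the x axis and PC2 (15.2%) on the y axis, one point per library. The 3 SETD8 libraries lie between -23.8 and -16.5 on PC1, and vector replicate 1 lies at -0.94, apart from vector replicates 2 and 3 at 25.7 and 39.3.

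KMT5A, the overexpressed gene, was 1.41-fold higher in the SETD8 libraries. It lies on chromosome 12 from 123383773 to 123409358 of GRCh38 (ENSG00000183955). Vector replicates 1, 2 and 3 had 46.0, 47.3 and 53.9 CPM and SETD8 replicates 1, 2 and 3 had 65.4, 66.2 and 75.5 CPM, so the groups did not overlap. The means were 49.1 ± 4.27 and 69.0 ± 5.63 CPM (SD, n = 3 each), with a log2 fold change of 0.49 (SE 0.10, edgeR adjusted p = 0.0156). Its processed pseudogenes KMT5AP2 and KMT5AP1, whose reads may be shared with KMT5A, had log2 fold changes of 1.06 (edgeR adjusted p = 0.0473) and 1.54 (edgeR adjusted p = 0.0266) at low counts, and KMT5AP3 had 0 counts in each library. KMT5A summed with its pseudogenes was 1.45-fold higher, and the split between these copies is uncertain. The sequence of the construct is not given in the sources used here, so transcripts from it that the counting would miss are not in these values. The KMT5A call was lost without vector replicate 2 (edgeR adjusted p = 0.0965) and without SETD8 replicate 1, 2 or 3 (edgeR adjusted p = 0.0661, 0.0579 and 0.0949).

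SETD8 overexpression was accompanied by a fall of 682 genes and a rise of 443 among 14370 genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and most of the larger changes were falls. At least 2-fold changes numbered 143, of which 105 were lower and 38 higher. The median fold was 1.48 for the genes that rose and 1.46 for those that fell. Protein-coding genes made up 1052 of the 1125 changed genes. Scaling by library totals alone shifted the median log2 fold change of all genes by 0.043 and gave 505 lower and 792 higher genes, so the share of falls moved from 60.6% to 38.9%. The groups did not overlap in 30.3% of all tested genes, against the 10% that chance gives for 3 against 3. The genes that fell had longer transcripts (median 4977 bases) than those that rose (2311 bases), against 3431 bases over all genes. The number of changed genes rested on single libraries, being 3509 without vector replicate 1, 72 without vector replicate 2, 1093 without vector replicate 3, and 11, 155 and 129 without SETD8 replicates 1, 2 and 3. Changes of at least 2-fold numbered 405, 25 and 95 without vector replicates 1, 2 and 3, and 8, 45 and 36 without SETD8 replicates 1, 2 and 3.

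The largest rises by the rule for named genes were led by GPS2, a subunit of nuclear corepressor complexes, on chromosome 17 (7311324 to 7315564), which rose from 5.84 ± 1.81 to 13.6 ± 2.52 CPM (SD, n = 3 each; log2 fold change 1.21, SE 0.22, edgeR adjusted p = 0.00861). H1-2, a linker histone gene, rose from 31.4 ± 8.55 to 64.8 ± 5.77 CPM (log2 fold change 1.04, SE 0.16, edgeR adjusted p = 0.00566). How fully poly(A) selection captured histone messengers is not known here, so the H1-2 value is uncertain. L3MBTL3, a reader of methylated lysine, rose by a log2 fold change of 0.96 and NRG1, a ligand of ERBB receptors, by 0.95. ABHD8 (1.17), KRTAP2-3 (1.13), the gamma-secretase subunit PSENEN (1.08), CAPN1-AS1 (1.04) and TMEM238 (0.96) rose as well. The largest falls included XDH, which encodes xanthine dehydrogenase and lies on chromosome 2 (31334321 to 31414715), from 10.8 ± 1.62 to 3.66 ± 0.51 CPM (log2 fold change -1.56, SE 0.19, edgeR adjusted p = 0.00262). SERPINA1, which encodes a secreted protease inhibitor, fell from 29.5 ± 10.1 to 9.53 ± 0.95 CPM (log2 fold change -1.63, SE 0.23, edgeR adjusted p = 0.00511). MRC2, a collagen-binding endocytic receptor, fell from 38.1 ± 14.0 to 14.9 ± 1.24 CPM (log2 fold change -1.35, SE 0.23, edgeR adjusted p = 0.00877). Log2 fold changes were -1.82 for DHRS2, -1.72 for MAB21L4, -1.49 for the nuclear noncoding RNA MALAT1, -1.44 for SERPINA5, -1.40 for PHYHIP, -1.37 for SH3PXD2A-AS1 and -1.29 for DYSF, which takes part in membrane repair. The strand setting of the counting is not given in the sources used here, so the antisense genes CAPN1-AS1 and SH3PXD2A-AS1 cannot be told apart from their partners. KRTAP2-3 has near-identical copies and lost its call with no low-count filter (edgeR adjusted p = 0.192). DHRS2 (edgeR adjusted p = 0.0499) lost its call with library totals (0.0645), DESeq2-type size factors (0.0545), KMT5A left out (0.0501), limma-voom (0.203), GC correction (0.0749) and length correction (0.114). DHRS2 and MALAT1 also lost their calls with the replicate block. Of these 19 calls, 10 were lost without vector replicate 2, 2 without vector replicate 3, and 18, 10 and 11 without SETD8 replicates 1, 2 and 3 (highest edgeR adjusted p = 0.134, 0.315, 0.147, 0.145 and 0.162).

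**Figure D2:**
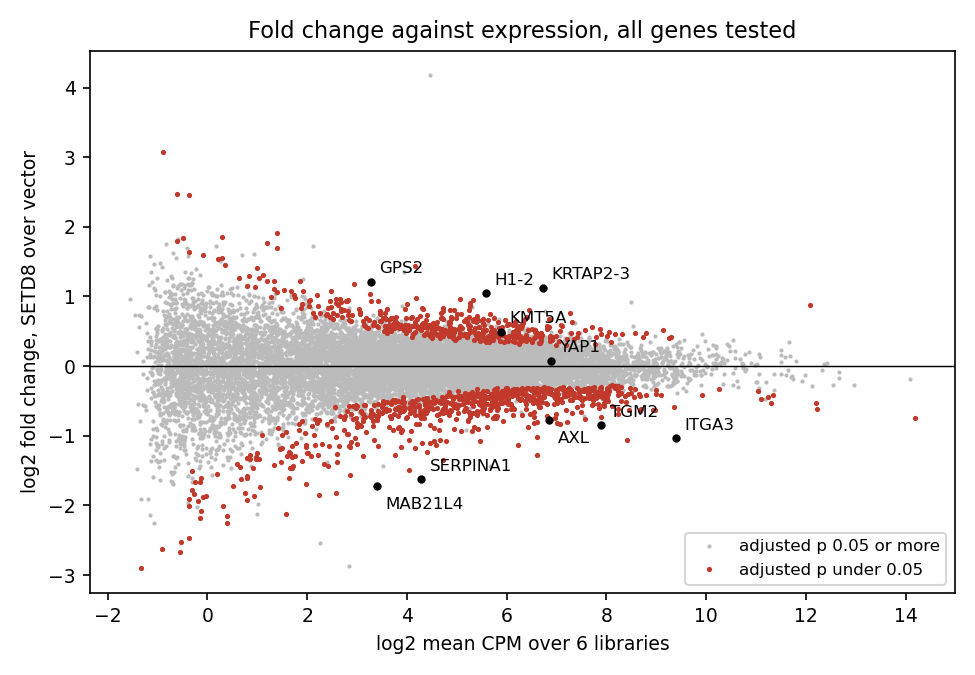
Log2 fold change of SETD8 over vector libraries (y axis) against log2 mean CPM over the 6 libraries (x axis) for the 14370 genes tested, with genes at adjusted p under 0.05 in red and named genes in black. Of the 1125 red genes, 682 lie below 0 and 443 above, with KMT5A at 0.49 and YAP1 at 0.08.

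YAP1 transcript did not pass the test, while 7 of the 19 tested YAP/TAZ target genes fell and 0 rose. YAP1 lies on chromosome 11 from 102110461 to 102233423 (ENSG00000137693). It had 116 ± 9.34 CPM in vector and 122 ± 4.38 CPM in SETD8 libraries (SD, n = 3 each). Its log2 fold change was 0.08 (SE 0.09, 95% interval -0.16 to 0.32, edgeR adjusted p = 0.600). The interval used the degrees of freedom of the libraries alone, so it is wider than the edgeR test itself would give. WWTR1, which encodes the paralog TAZ, fell from 74.3 ± 10.3 to 56.5 ± 5.66 CPM (log2 fold change -0.39, SE 0.11, edgeR adjusted p = 0.0497). Among the targets, the receptor tyrosine kinase gene AXL fell from 146 ± 9.90 to 85.3 ± 9.10 CPM (log2 fold change -0.77, SE 0.10, edgeR adjusted p = 0.00318) and was called whichever library was left out. DOCK5 fell by a log2 fold change of -0.55, AMOTL2 by -0.48 and PTPN14 by -0.42. CCN2, a secreted matricellular protein gene, fell from 10.9 ± 2.35 to 6.44 ± 1.69 CPM (log2 fold change -0.76, SE 0.21, edgeR adjusted p = 0.0457), although its groups overlapped. CCN1 (-0.13, edgeR adjusted p = 0.559) and ANKRD1 (-1.34, edgeR adjusted p = 0.0907) did not pass. Neither did TEAD1 (-0.21), TEAD2 (-0.07), TEAD3 (0.07) and TEAD4 (0.03), which encode the DNA-binding partners of YAP (edgeR adjusted p = 0.212, 0.779, 0.775 and 0.868). TEAD1 passed without vector replicate 1 (log2 fold change -0.30), and ANKRD1 passed without vector replicate 1 (-1.77) and with no low-count filter (-1.34). The median log2 fold change of the list was -0.42, with camera adjusted p = 1.68e-05, and 11 members were lower when adjusted over the list alone. With an estimated correlation the adjusted p was 0.683, and fry gave an adjusted p of 0.165. The list of Hippo pathway components also passed camera as lower, with 5 lower and 1 higher of 27 and the same counts adjusted over the list alone. Its median was -0.16 (camera adjusted p = 0.00621; adjusted p = 0.683 with an estimated correlation). Their falls were AMOTL1 (-0.53), AMOTL2, NF2 (-0.40), PTPN14 and WWTR1, while SAV1, a scaffold of the kinase cascade named after its value was seen, rose by 0.37. AMOTL2, PTPN14 and LATS2 stand in both lists. The Hippo median was -0.094 without vector replicate 3 (camera adjusted p = 0.0384). With length correction it was -0.064 and the list lost its call (camera adjusted p = 0.194), as did PTPN14 (edgeR adjusted p = 0.0973). WWTR1 lost its call with library totals (edgeR adjusted p = 0.0704) and limma-voom (adjusted p = 0.0521). Of the 9 genes called here, 8, 2, 8, 8 and 6 lost their call without vector replicates 2 and 3 and SETD8 replicates 1, 2 and 3 (highest edgeR adjusted p = 0.179, 0.0820, 0.199, 0.177 and 0.104).

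**Figure D3:**
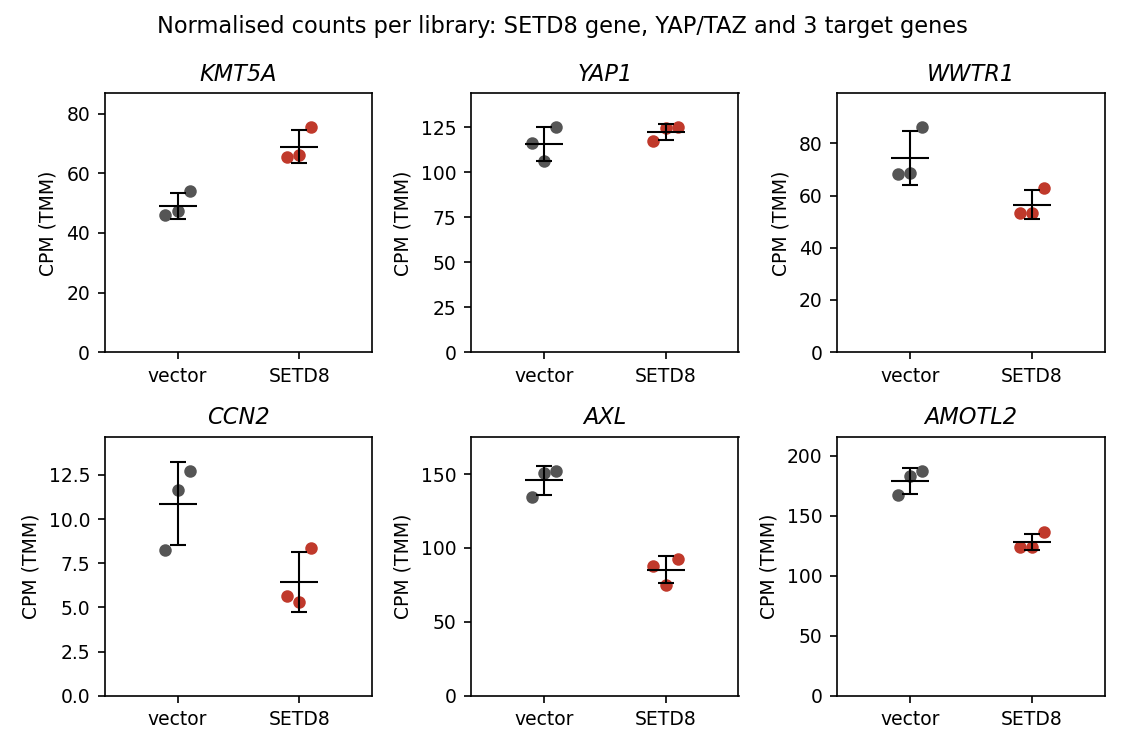
TMM-normalised CPM (y axis, from 0) of KMT5A, YAP1, WWTR1, CCN2, AXL and AMOTL2 in vector (grey) and SETD8 (red) libraries, one point per library, with black bars for the mean ± SD of 3. KMT5A was higher in each SETD8 library, YAP1 and CCN2 overlapped between groups, and WWTR1, AXL and AMOTL2 were lower in each SETD8 library.

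The mesenchymal, intestinal differentiation, Wnt target and NF-kappaB target lists passed camera as lower with SETD8, and none did with an estimated correlation. Members not tested were 7 of 19 mesenchymal, 17 of 25 intestinal, 5 of 22 Wnt and 7 of 20 NF-kappaB genes. Of 12 tested mesenchymal genes, 5 fell and 0 rose (6 lower adjusted over the list alone), with a median log2 fold change of -0.67 (camera adjusted p = 7.12e-04; adjusted p = 0.375 with an estimated correlation). THBS1, which encodes a matrix glycoprotein, fell from 37.5 ± 9.46 to 17.8 ± 2.93 CPM (SD, n = 3 each; log2 fold change -1.08, SE 0.18, edgeR adjusted p = 0.00699). The fibronectin gene FN1 (-0.92) fell, as did S100A4 (-0.41, named after its value was seen) and VIM (-1.60), which had a mean of 1.39 CPM in vector and 0.45 CPM in SETD8 libraries. Of 8 tested intestinal differentiation genes, the adhesion molecule gene CEACAM1 (-1.28) and the transcription factor gene HNF4A (-0.57) fell and 0 rose. The intestinal list had 5 lower adjusted over the list alone (camera adjusted p = 0.00540; adjusted p = 0.375 with an estimated correlation; fry adjusted p = 0.00311). Of 17 tested Wnt targets, NOTUM, a secreted Wnt antagonist gene (-1.05), and SOX9 (-0.44) fell and 0 rose. The Wnt list had 6 lower adjusted over the list alone (camera adjusted p = 0.00621; adjusted p = 0.683 with an estimated correlation). Of 13 tested NF-kappaB targets, the cytokine gene LIF (-0.71) and the feedback inhibitor gene TNFAIP3 (-0.92) fell and 0 rose. The NF-kappaB list had 2 lower adjusted over the list alone (camera adjusted p = 0.0171; adjusted p = 0.683 with an estimated correlation). The Wnt median was -0.21, but -0.33 without vector replicate 1 and -0.13 without vector replicate 3 (camera adjusted p = 0.00203 and 0.0384). The NF-kappaB list lost its call without vector replicate 2 (camera adjusted p = 0.0901), and HNF4A with length correction (edgeR adjusted p = 0.0650). Of the 10 genes named here, 9, 10, 7 and 7 lost their call without vector replicate 2 and SETD8 replicates 1, 2 and 3 (highest edgeR adjusted p = 0.218, 0.178, 0.126 and 0.157).

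**Figure D4:**
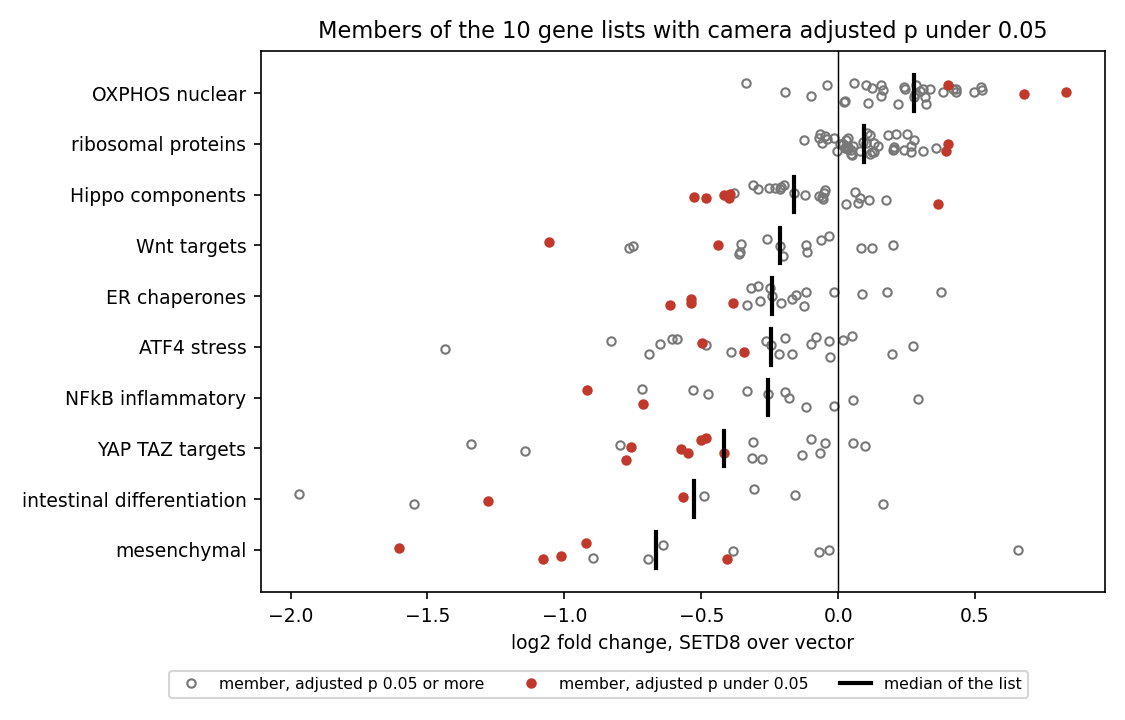
Log2 fold change of SETD8 over vector (x axis) for each tested member of the 10 lists with camera adjusted p under 0.05 (y axis, one list per line), with members at adjusted p under 0.05 filled in red, other members open and the list median as a black bar. Medians run from -0.67 for mesenchymal genes to 0.28 for nuclear-encoded oxidative phosphorylation genes, and the other list above 0 is that of ribosomal proteins at 0.10.

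The lists of endoplasmic reticulum chaperones and ATF4 stress genes passed camera as lower with SETD8, and those of nuclear-encoded oxidative phosphorylation and ribosomal protein genes as higher, though few members passed and none of the lists did with an estimated correlation. Of 19 chaperone genes, 4 fell and 0 rose (8 lower adjusted over the list alone), with a median log2 fold change of -0.24 (camera adjusted p = 7.12e-04; adjusted p = 0.683 with an estimated correlation). HSP90B1, which encodes the chaperone endoplasmin, fell from 500 ± 95.3 to 327 ± 19.9 CPM (log2 fold change -0.61, SE 0.12, edgeR adjusted p = 0.0152, n = 3 each), and the disulfide isomerase genes PDIA4 (-0.54) and PDIA6 (-0.38) and the co-chaperone gene DNAJC3 (-0.54) fell. Of 23 ATF4 genes, PCK2 (-0.50) and PHGDH (-0.35), which encode metabolic enzymes, fell and 0 rose. The ATF4 list had 2 lower adjusted over the list alone (median -0.24; camera adjusted p = 0.0293; adjusted p = 0.683 with an estimated correlation). Of 34 oxidative phosphorylation genes, NDUFB3 (0.68), COX6C (0.40) and SDHD (0.83), subunits of respiratory complexes, rose and 0 fell. The oxidative phosphorylation list had 3 higher and 1 lower adjusted over the list alone, with a median of 0.28 (camera adjusted p = 3.30e-05; adjusted p = 0.683 with an estimated correlation). Of 44 ribosomal protein genes, RPS28 (0.39) and RPLP2 (0.40) rose and 0 fell. The ribosomal list had 0 adjusted over the list alone (median 0.10; camera adjusted p = 0.00540; adjusted p = 0.841 with an estimated correlation). Without vector replicate 3 the oxidative phosphorylation median was 0.16 (camera adjusted p = 0.00587). The ribosomal median was 0.16 without vector replicate 1 (camera adjusted p = 2.89e-05) and 0.060 without SETD8 replicate 1 (0.0445). The ribosomal list lost its call without vector replicate 3 (camera adjusted p = 0.629, median -3.50e-04) and with length correction (0.959, median -0.0045), and the ATF4 list without vector replicates 2 and 3 (0.133 and 0.0604) and SETD8 replicates 1 and 2 (0.0533 and 0.0627). COX6C, RPS28 and RPLP2 lost their calls with length correction (edgeR adjusted p = 0.116, 0.0661 and 0.0953), SDHD with GC correction (0.0883), and PCK2 and PHGDH with library totals (0.0520 and 0.0535). Of these 11 genes, 11, 2, 11, 10 and 10 lost their call without vector replicates 2 and 3 and SETD8 replicates 1, 2 and 3 (highest edgeR adjusted p = 0.217, 0.0713, 0.173, 0.185 and 0.153).

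Lists of chromatin and cell cycle genes did not pass the list test with the main settings, though single members changed. Of 14 genes in the list for H4K20 methylation and methyltransferases, L3MBTL3 and KMT5A rose and the methyltransferase gene NSD2 fell by -0.39. The H4K20 list had 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.466). Of 12 histone genes, H1-2 (1.04) and H2BC5 (0.56) rose, while H1-4 (-2.16, from 2.14 to 0.48 CPM) and HIST1H3B (-2.52, from 1.18 to 0.20 CPM) fell. The histone list had 4 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.942). Some histone genes have near-identical copies. The libraries were also poly(A)-selected, and how fully histone messengers were captured is not known here, so values of this list are uncertain. Of 28 mitosis genes, the proliferation marker gene MKI67 fell from 501 ± 71.1 to 320 ± 30.4 CPM (log2 fold change -0.64, SE 0.11, edgeR adjusted p = 0.00807, n = 3 each) and CENPF fell by -0.63. The mitosis list had 2 lower adjusted over the list alone (camera adjusted p = 0.646), with a median of 0.01 and a mean of -0.04. Of 31 replication genes, the helicase subunit gene MCM2 (-0.38) and the polymerase gene POLA1 (-0.45) fell. The replication list had 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.153). In the list for the ubiquitin ligase that degrades SETD8, 0 of 10 genes passed by either adjustment (camera adjusted p = 0.942, median -0.07, mean 0.02). That list also holds SKP1, which is not a subunit of this ligase. Of 29 p53 targets, the apoptosis genes PMAIP1 (0.47) and BBC3 (0.59), TP53INP1 (0.46) and PHLDA3 (0.42, named after its value was seen) rose and FDXR (-0.48) fell. The p53 list had 6 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0590). The replication list was called lower with length correction (camera adjusted p = 0.0137) and without vector replicate 3 (0.0215) or SETD8 replicate 3 (0.0120). The p53 list was called higher with library totals (camera adjusted p = 0.0476), no low-count filter (0.00853) and without vector replicate 1 (0.0352), vector replicate 2 (0.0282) or SETD8 replicate 1 (0.0415). With length correction NSD2 and H2BC5 lost their calls (edgeR adjusted p = 0.0580 and 0.0656). Of the 16 genes called here, 14, 16, 14 and 13 lost their call without vector replicate 2 and SETD8 replicates 1, 2 and 3 (highest edgeR adjusted p = 0.166, 0.143, 0.156 and 0.132).

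Stress and signalling lists also missed the list test, though each but the cholesterol list was called under some other setting. Of 20 NRF2 targets, the antioxidant enzyme genes GCLM (0.60) and HMOX1 (0.58), the ferritin gene FTL (0.88) and AKR1B10 (1.22, named after its value was seen) rose and the exporter gene ABCC3 (-1.17) fell. The NRF2 list had 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.108). Of 28 interferon genes, IFI6 rose from 27.3 ± 4.99 to 52.7 ± 3.37 CPM (log2 fold change 0.94, SE 0.13, edgeR adjusted p = 0.00438, n = 3 each), IFI35 (0.62) and ISG20 (0.59) rose and MX1 (-0.98) fell. The interferon list had 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.105). Of 15 heat shock genes, the chaperone genes HSPA8 (-0.41), HSP90AA1 (-0.44) and DNAJB1 (-0.31) fell. The heat shock list had 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0590). Of 21 MAPK genes, FOSL1 (-0.43), SPRY4 (-0.70) and EGR2 (-2.01) fell. EGR2 had means of 1.99 and 0.50 CPM and its groups overlapped. The MAPK list had 5 lower adjusted over the list alone (camera adjusted p = 0.0931). Of 24 cholesterol genes, 2 fell, among them the sterol synthesis gene LSS (-0.33; camera adjusted p = 0.759, with 2 lower adjusted over the list alone). Of 25 hypoxia genes ADM (0.58) rose (camera adjusted p = 0.220, with 1 higher adjusted over the list alone). Heat shock genes were called lower with length correction (camera adjusted p = 0.00603), no low-count filter (0.00853) and without vector replicate 3 (0.00587), SETD8 replicate 1 (0.0454) or SETD8 replicate 3 (0.0204). MAPK genes were called lower with length correction (camera adjusted p = 0.04997), no low-count filter (0.0172) and without vector replicate 1 (0.00144) or SETD8 replicate 3 (0.0468). Hypoxia genes were called lower without vector replicate 1 (camera adjusted p = 0.00662). Interferon genes were called higher with no low-count filter (camera adjusted p = 0.0141) and without vector replicate 2 (0.00893), and NRF2 targets with no low-count filter (0.00981) and without SETD8 replicate 2 (0.0305). FTL, which has many pseudogene copies, lost its call with no low-count filter (edgeR adjusted p = 0.278), MX1 with library totals (0.0520) and DESeq2 (0.0634), LSS and DNAJB1 with library totals (0.0664 and 0.0570). EGR2 lost its call with limma-voom (0.114), and AKR1B10 with limma-voom (0.0857) and length correction (0.0570). Of these 17 genes, 14, 5, 16, 12 and 14 lost their call without vector replicates 2 and 3 and SETD8 replicates 1, 2 and 3 (highest edgeR adjusted p = 0.200, 0.152, 0.206, 0.176 and 0.190).

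Lists that report cell identity and RNA quality did not pass either with the main settings. Of 18 epithelial genes, the tight junction genes CLDN4 (0.46) and CLDN7 (0.43) rose and the cadherin gene CDH1 fell from 117 ± 21.5 to 80.7 ± 5.43 CPM (log2 fold change -0.54, SE 0.12, edgeR adjusted p = 0.0218, n = 3 each). The epithelial list had 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.525). Of 13 mitochondrially encoded messenger genes, MT-CO3 fell (-0.53; 2 lower adjusted over the list alone; camera adjusted p = 0.108), and the ribosomal RNAs MT-RNR1 (-0.62) and MT-RNR2 (-0.74), named after their values were seen, fell. The mitochondrial messenger list was called lower with length correction (camera adjusted p = 0.00141, with the median moving from -0.11 to -0.35), no low-count filter (0.0111) and without vector replicate 2 (7.49e-04) or SETD8 replicate 2 (0.0170). Its median was -0.032 without vector replicate 3 (camera adjusted p = 0.530) and -0.011 without SETD8 replicate 1 (0.702). Of 5 nuclear and stress noncoding RNAs, GAS5 (0.44) and SNHG1 (0.40) rose and MALAT1 (-1.49) fell. SNHG1 and MALAT1 lost their calls with the replicate block. The noncoding RNA list had 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.969). Of 6 tested HEK293 marker genes, 0 passed over all genes. The HEK293 list had 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.969; median 0.01, mean -0.13). Other cell type markers were mostly too low to test. Tested members were 3 of 11 fibroblast, 2 of 9 endothelial and 2 of 14 immune genes, of which only HLA-DRA passed (-0.76, from 9.51 to 5.60 CPM, edgeR adjusted p = 0.0456; 2 lower adjusted over the list alone), and its call was lost with library totals (0.0515) and limma-voom (0.0530). Of the 10 genes called here, 9, 1, 10, 9 and 10 lost their call without vector replicates 2 and 3 and SETD8 replicates 1, 2 and 3 (highest edgeR adjusted p = 0.222, 0.0522, 0.155, 0.155 and 0.200).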

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

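The GC and length corrections were chosen after seeing the data; the other settings were fixed beforehand. YAP1 did not pass under any setting, and KMT5A passed under each setting that kept it and all 6 libraries. None of the 106 called genes selected by the rule or named in the text, KMT5A aside, changed sign under any setting in which it had a value, but calls lost were 0, 80 and 14 without vector replicates 1, 2 and 3 and 95, 73 and 73 without SETD8 replicates 1, 2 and 3, fits with fewer samples. Leaving out each library gave 11 to 3509 changed genes (1 to 1771 higher, 10 to 1738 lower) and 8 to 405 at 2-fold (0 to 155 higher, 8 to 250 lower), with KMT5A at 0.42 to 0.57. Without a low-count filter, 2000 genes were called (949 higher, 1051 lower), 233 of them at 2-fold (63 higher, 170 lower), and 16 lists. Higher genes numbered 792 with library totals, 691 with DESeq2 and 709 with GC correction and the replicate block. With an estimated correlation the YAP/TAZ list had adjusted p = 0.683 and 0 lists were called; with fry these were 0.165 and 1. For these the cause was not tested.

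Reversals concerned results that did not pass. Over the left-out libraries, TEAD2 ranged from -0.19 to 0.057, CCN1 from -0.22 to 0.026 and TEAD3 from -0.040 to 0.20, and TEAD4 was -0.13 with length correction and -0.12 with the block added. Lists that turned had the adjusted p-values that follow. They were, over the left-out libraries, cholesterol 0.221 to 0.977, the SETD8 ligase 0.699 to 0.990, HEK293 markers 0.813 to 0.990, noncoding RNAs 0.724 to 0.990, mitosis 0.147 to 0.893 and histones 0.813 to 0.992. With length correction, without and with the block, they were noncoding RNAs 0.809 and 0.792, H4K20 0.728 and 0.673, and HEK293 0.726 and 0.673. Noncoding RNAs also turned with fry (0.860) and no filter (0.909), HEK293 with library totals (0.988) and the strict filter (0.980), and histones with the strict filter (0.816), the block (0.972) and GC correction with the block (0.947). The cause was not tested.

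The replicate number as a block gave 1177 changed genes (532 higher, 645 lower) against 1125. With the block, DHRS2, MALAT1, PHGDH, SNHG1, DNAJB1 and MX1 no longer passed (edgeR adjusted p = 0.0557 to 0.0659), and the MAPK list did (camera adjusted p = 0.0202; 0.0404 with GC correction and 0.00865 with length correction added). Same-numbered libraries had correlations of their deviations, across genes, of 0.025, 0.0078 and -0.064, and vector replicates 1 and 3 correlated best with other numbers. No pairing by number was seen, though so few libraries cannot exclude one. Depth, 17056672 to 20471843 counts per library, limits genes of few counts.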

Other observations

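The families and single genes in this part were chosen after their values were seen, as were the tests of the YAP1 transcript, of length for the YAP/TAZ list, and of a swap, a mixture and length for vector replicate 1. Members of several families of matrix and cell surface genes fell. No family kept its call with an estimated correlation, while each of the 7 given here passed fry. Laminin genes, which encode basement membrane proteins, fell in 8 of 11 tested, among them LAMC3 (-0.89) and LAMA5 (-0.83). The laminin median log2 fold change was -0.55 (camera adjusted p = 2.53e-07, adjusted p = 0.109 with an estimated correlation, fry adjusted p = 0.0232). These 11 include a pseudogene, which had the only positive fold change. Integrin genes fell in 6 of 18 (median -0.56; camera adjusted p = 4.19e-06; adjusted p = 0.151 with an estimated correlation; fry adjusted p = 0.0243), with ITGA3 (-1.04, SE 0.12, edgeR adjusted p = 0.00262) and ITGB4 (-1.06, SE 0.13, edgeR adjusted p = 0.00262), which encode laminin receptor subunits. Collagen genes fell in 7 of 18 (median -0.46), including COL18A1 (-0.80), ADAM and ADAMTS protease genes in 5 of 15, semaphorins and plexins in 7 of 22, serpins in 5 of 16, and ephrins and their receptors in 5 of 15, with EFNA3 (0.83) higher (camera adjusted p = 4.06e-05, 4.19e-06, 4.19e-06, 4.28e-04 and 0.00701; each 0.109 with an estimated correlation). Their fry adjusted p-values were, in that order, 0.0141, 0.0232, 0.0159, 0.0141 and 0.0141. LAMA5 lost its call with GC correction (edgeR adjusted p = 0.0603). Of these 6 named genes, 2, 1, 4, 1 and 2 lost their call without vector replicates 2 and 3 and SETD8 replicates 1, 2 and 3 (highest edgeR adjusted p = 0.0858, 0.0520, 0.0988, 0.0754 and 0.129).

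Some genes for the mitochondrial ribosome and for snoRNA hosts rose, and neither family kept its camera call with an estimated correlation, while snoRNA hosts alone passed fry. Mitochondrial ribosomal protein genes rose in 4 of 74 (median 0.24; camera adjusted p = 5.46e-11; adjusted p = 0.313 with an estimated correlation; fry adjusted p = 0.127), including MRPL33 (0.49), which lost its call with length correction (edgeR adjusted p = 0.0947). Of 22 snoRNA host genes, 6 rose and 0 fell (median 0.40; camera adjusted p = 8.35e-05; adjusted p = 0.147 with an estimated correlation; fry adjusted p = 0.0243), including SNHG7 (0.68) and SNHG32 (0.76). Of these 3 named genes, 2, 3, 3 and 2 lost their call without vector replicate 2 and SETD8 replicates 1, 2 and 3 (highest edgeR adjusted p = 0.0858, 0.0997, 0.0894 and 0.0951). Proteasome genes had a median of 0.15, with 0 of 36 called (camera adjusted p = 0.00195; adjusted p = 0.494 with an estimated correlation; fry adjusted p = 0.265), and the family lost this call with length correction (0.166). Zinc finger and keratin genes did not pass (camera adjusted p = 0.620 each). Calls held in each of the 6 fits that left out a library for 11 genes. Of these, ITGA3, ITGB4, TGM2, AXL, TNS4, ADAM19, SUSD2, BAIAP3, NES and XDH fell and IFI6 rose.

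The count of changed genes was 1125, and 143 at 2-fold, where the highest among the 9 other splits of the 6 libraries was 0 for both. Thus 1 of 10 splits reached each count, and 10 splits are too few for a share under 0.05. The other splits mix the groups, so a difference between the groups would raise the spread within their sides and lower their counts. Across genes, which are not independent, fold change fell with transcript length (Spearman -0.33) and hardly with GC (-0.04). Called genes were 166 higher and 37 lower in the shortest of 5 equal classes and 36 higher and 268 lower in the longest. By GC, called genes were 124 higher and 45 lower in the lowest class and 75 higher and 218 lower in the highest. With each library's length trend removed, 84.1% of the calls kept their direction and threshold, and with the GC trend removed 96.2%. This argues against either trend, as these corrections model it, as the whole cause. Deviations of genes correlated with transcript length (Spearman) at -0.16, 0.18 and 0.48 in vector replicates 1, 2 and 3. In SETD8 replicates 1, 2 and 3 the values were -0.28, -0.22 and -0.31. By this correlation the libraries stood in the same order as on the first principal component. With transcript GC the correlations were 0.35, 0.12 and -0.21 in vector replicates 1, 2 and 3. In SETD8 replicates 1, 2 and 3 they were -0.09, 0.02 and -0.03. A difference between libraries linked to length thus stays open, as does a difference between vector libraries linked to GC. A batch of library preparation stays open, as the labels give none, and an effect of SETD8 on these genes remains a hypothesis.

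The YAP/TAZ list was lower while YAP1 transcript had a lower 95% limit of -0.16, above the list median of -0.42. This argues against a fall of YAP1 transcript as large as that median. Whether targets move in proportion to YAP1 transcript was not tested, so a smaller fall is not excluded as the source. WWTR1 at -0.39 (edgeR adjusted p = 0.0497) leaves less TAZ transcript open. The list kept its camera call with the GC trend (adjusted p = 2.93e-05) and the length trend (3.34e-05) removed. Without these corrections its call was lost with an estimated correlation (camera adjusted p = 0.683) and with fry (adjusted p = 0.165). Of 10 splits, 2 with the real one gave a camera p as small as its 6.45e-07, and the smallest of the others, 7.21e-08, set vector replicate 1 with SETD8 replicates 1 and 2 against the rest. Of the lists, 10 were called in the real split and up to 13 in another, so that 4 of 10 splits called as many; 10 splits are too few for a share under 0.05. Lower YAP protein activity may contribute, as the title of the series would have it, but protein was not analysed here. Camera at a preset correlation also called lists in splits with 0 changed genes. Those splits mix the groups unevenly and keep part of the real contrast, so lists called there are not shown to be false calls.

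Vector replicate 1 lay toward the SETD8 libraries. Each library was placed on the 500 leading genes of a comparison made without it. There 0 is the mean of the vector libraries and 1 that of the SETD8 libraries, the placed library left out. Vector replicate 1 stood at 0.64, against 0.03 and -0.15 for vector replicates 2 and 3. The genes and means differ with the library placed, so these positions do not share a common scale. Each SETD8 library stood at 0.719 or higher, so that no partner for a swap was found. A mixture with SETD8 cells at the position of vector replicate 1 would give 62.3 CPM of KMT5A. The observed 46.0 CPM was 3.07 SD lower (pooled SD 5.33 CPM, a test on this gene alone, as counted). That SD is the spread within groups and leaves out the error of the prediction, which applied a log2-scale position to CPM. The 3.07 SD thus overstates the evidence against a mixture. With the GC or length trend removed, vector replicate 1 still stood 0.634 or 0.622 above the higher of the other vector libraries, each on its own scale. A difference in culture or library preparation may remain, and no biological explanation was tested.

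Along the chromosomes, no window of 20 megabases among 153 had a median log2 fold change more than 0.155 from that of all genes. This was under the bound of 0.3 set for a copy-number difference. Such medians may miss a change confined to a shorter stretch or to part of the cells. BOLA2B had 71.2, 2.38 and 51.4 CPM in SETD8 replicates 1, 2 and 3 and at most 3.65 CPM in the vector libraries (log2 fold change 4.18, edgeR adjusted p = 0.167), and its near-identical copy BOLA2 stayed under 0.5 CPM in each library.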
